A study of Mus musculus with 16 samples.

How the data were processed

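BLISS libraries of AB22 cells, 8 from shCTRL and 8 from shHMGB1 cells at 4 doses, were analysed from the deposited lists of break ends, one per library. Per the labels' protocols, free DNA ends were blunted and ligated to adapters inside fixed cells, the genomic DNA was sonicated and transcribed in vitro, and small RNA libraries were made from that RNA. The submitters' processing notes name Trimmomatic 0.32, BWA 0.7.5-r404, SAMtools, UMI-tools and bedtools and the build mm10, without giving their order or settings. The deposited files give, for each cluster of ends, its interval, the end position of each molecule and a count, and the authors' counts are of molecules left after duplicates were removed by their molecular identifiers. The values are raw counts of break ends, not normalised by the authors. The files keep no strand. Other data types that the series' design names, RNA-seq and ATAC-seq, were not analysed here.

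Each molecule was placed at its own end position, and ends on the main chromosomes were used. The mitochondrial genome held 0.217% to 0.478% of a library's ends and unplaced scaffolds 0.411% to 0.745%, and both were left out. Positions are given 1-based in mm10. Genes came from GENCODE M21, with 21910 protein-coding and 10142 long noncoding genes on the main chromosomes, 32052 in all. An end counted for a gene when it fell between the gene's start and end, exons and introns together, and an end in overlapping genes counted for each of them. Region shares put each end in 1 class by priority, first within 1 kb of a protein-coding TSS, then exon, intron and intergenic. Densities are CPM per kb, where exon and intron densities of a list used genes that have introns of their own. That last choice replaced a first version that included Malat1 and Neat1, which lack introns, and was made after seeing the first values. Dense regions are the 32 regions within 1 kb of a cluster of at least 1000 ends, and they held 18.3% to 26.7% of a library's ends.

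Libraries were grouped by the hairpin, dose and replicate number in their labels. Totals, region shares and pair ratios were compared by exact two-sided permutation tests. These enumerated the labels within each dose (comparison of lines) or within each line (irradiated against 0 Gy). Benjamini-Hochberg adjustment was over the 4 regions and 2 comparisons, and over the 5 small RNA classes and 2 comparisons. Differences between lines in the irradiation response of these values were tested with hairpin labels exchanged within each dose. That scheme assumes no difference between lines of any kind, and the few arrangements at 0 Gy left it little power. Genes and 1 Mb windows were tested with edgeR 4.0.16 (R 4.3.3) by glmQLFit and glmQLFTest on 8 group means, with TMM factors and filterByExpr, at a Benjamini-Hochberg adjusted p under 0.05. All 8 groups shared 1 estimate of the spread. Genes passing the filter numbered 12582 and windows 2578. Shown levels are CPM, the counts scaled to a common library size, with mean and SD over libraries, and log2 changes are given with their standard errors. The gene lists were highly transcribed genes, ribosomal proteins, fibroblast, mesothelial, immediate early, p53 target, double-strand break repair, long fragile, neuronal, blood cell, histone, olfactory receptor and vomeronasal receptor genes. Of these 13 lists, 12 had at least 5 tested members. They were tested by camera (limma 3.58.1) with the preset correlation of 0.01 and with an estimated one, on log2 CPM with a prior count of 2, and list medians are from those values.

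The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named up to 12 genes with the smallest p in each direction of each comparison, leaving out predicted genes, the 15 densest genes in unirradiated shCTRL with a mean count of at least 20, Hmgb1, and of each list the 3 members with the most ends and any member past the test. For windows it took 5 in each direction. Alternatives were DESeq2 1.42.0 (test and size factors), library totals without TMM, no filter on low counts, distinct positions, windows of 2.5 kb on each side of the TSS, 100 kb windows, libraries thinned to 131430 ends, autosomes only, the replicate number as a block, only the libraries compared, and each library left out in turn. Ends outside exons and dense regions, at most 3 ends per position for shares, genes and windows, and shares without dense regions were added after seeing the data. So were a block of replicate number within each line (genes, windows and lists), libraries summed by line and number (genes and windows), and the test of replicate number within a line against all 8 divisions of its libraries with 1 of each dose on each side. For irradiation the block within each line was also fitted on 80 splits that exchanged doses only within a line and number. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

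Depth limits single genes more than windows. The count models were tested on simulated data with 100 genes or windows changed 1.5-fold and 100 changed 2-fold. For the comparison of lines 12% and 38% of the changed genes were recovered and 2 unchanged genes were called. For irradiation 5% and 25% were recovered with 5 unchanged genes called, and for the interaction 0% and 0%. For windows 99% and 100% were recovered in each comparison, with 7 and 15 unchanged windows called. The simulated libraries varied independently, without the structure by replicate number described below. These shares therefore do not give the power in the real libraries. The 2 libraries of a group correlated at r = 0.706 to 0.892 across genes, which are not independent replicates, and differed by more than sampling noise in each group (chi-square per degree of freedom 2.67 to 5.29), so no library was counted as a duplicate of another.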

Results

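AB22 is a mouse cell line from a malignant mesothelioma, a tumour of the lining of the body cavities. BLISS maps DNA double-strand breaks by ligating an adapter to each free DNA end in fixed cells and sequencing outward from it. The libraries compare cells carrying a control hairpin (shCTRL) with cells carrying a hairpin against HMGB1 (shHMGB1), a DNA-bending chromatin protein. The question named by the study's title is whether nucleosomes shield DNA from breaks made by irradiation. Cells of both lines, held in G1, were irradiated with gamma rays at 0 (no exposure), 3, 5 and 10 Gy, with 2 libraries in each of the 8 groups and 16 libraries in all. The libraries held 132390 to 1020770 break ends after removal of duplicate molecules, with a median of 813725. The main chromosomes held 11380784 ends in all. The labels call the libraries of a group biological replicates without saying how far apart they were grown, so the p-values measure the spread between these samples.

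Libraries with the same replicate number within a line shared more than the number. Between replicates 1 and 2, 80 genes differed within shCTRL and 49 within shHMGB1 (edgeR with a block of replicate number within each line, adjusted p under 0.05). Between the lines, 31 genes differed without that block and 134 with it. The 7 other ways of dividing a line's libraries with 1 of each dose on each side gave at most 1 gene in shCTRL and 0 in shHMGB1. For 1 Mb windows the counts were 120 and 17, against at most 0 and 1. In shCTRL the intron share was 37.2 ± 0.228% in replicate 1 and 41.8 ± 0.362% in replicate 2, and the share near transcription starts 16.7 ± 1.52% and 12.4 ± 1.48% (SD, n = 4 each). This structure was tested after seeing the data, and its source is not given. If the libraries of a number came from 1 culture or preparation, each line has 2 independent units and not 8. An exact test of 2 against 2 cannot go below p = 0.333, and every p-value below for the comparison of lines is then too small. With libraries summed by line and number, 3 of the 31 genes kept their call.

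Hmgb1, the targeted gene, held 40.002 ± 8.32 CPM (break ends scaled by library) in shCTRL and 43.8 ± 13.7 in shHMGB1 (SD, n = 8 each). The log2 difference was 0.16 ± 0.20 (SE; edgeR quasi-likelihood adjusted p = 0.844). Hmgb1 lies at chromosome 5, 149046702 to 149184489 (mm10). Break ends in a gene do not measure its transcript, so this value does not check the knockdown.

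Libraries of shHMGB1 cells held more break ends than those of shCTRL cells. The shHMGB1 libraries averaged 841855 ± 99968.9 ends on the main chromosomes and the shCTRL libraries 580743 ± 274485 (SD, n = 8 each). Within doses the geometric mean ratio was 1.66, higher in shHMGB1 at 4 of 4 doses, with an exact stratified permutation p = 0.0185 (two-sided). By dose the ratio was 1.79 at 0 Gy, 2.33 at 3 Gy, 1.68 at 5 Gy and 1.07 at 10 Gy. With 2 libraries against 2, a single dose cannot go below p = 0.333 in an exact test. The log2 difference of 0.73 was 0.38 without shCTRL 3 Gy replicate 2 (exact p = 0.0386) and 1.08 without shCTRL 3 Gy replicate 1 (exact p = 0.00463). The call ended without shHMGB1 3 Gy replicate 1 (log2 difference 0.70, exact p = 0.154) and without shHMGB1 3 Gy replicate 2 (0.76, exact p = 0.127). A total also depends on the cells used and on sequencing, which were not given in the sources used here.

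Dose did not move the totals beyond the spread between libraries. Irradiated libraries held 1.16 times the ends of unirradiated ones (n = 12 and 4; log2 0.21, exact permutation p = 0.631). With single libraries left out the log2 value ran from 0.12 to 0.41, highest without shCTRL 3 Gy replicate 2 (exact p = 0.0612). In shCTRL the mean was 438591 ± 65693 at 0 Gy and 852198 ± 8903.18 at 10 Gy (SD, n = 2), and the slope over 8 libraries was 0.11 log2 units per Gy. Its Pearson r was 0.475 (exact permutation p = 0.240, also after adjustment over 2 lines) and Spearman's rho 0.488 (exact p = 0.247). Without the 2 libraries at 10 Gy, the farthest in dose, r was 0.0705, so the relation in shCTRL rested on them. In shHMGB1 the slope was 0.02, r 0.517 (exact p = 0.187, adjusted 0.240) and rho 0.488 (exact p = 0.247), and r without 10 Gy was 0.316. The shCTRL library with the fewest ends, 3 Gy replicate 2, held 131430, against 927413 in its replicate. The response to irradiation did not differ detectably between the lines (log2 difference of differences −0.15, exact p = 0.877).

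**Figure D1:**
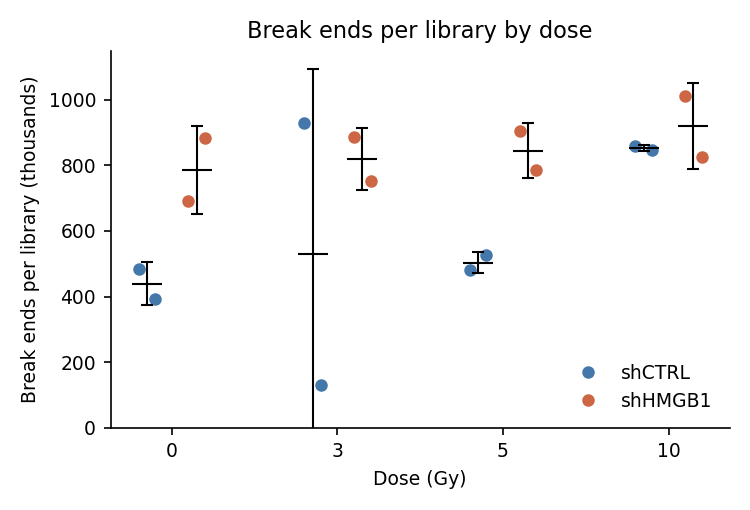
Break ends per library (y axis, in units of 1000) against dose (Gy, x axis) for shCTRL and shHMGB1; points are libraries and bars mark the mean ± SD of 2. The shHMGB1 libraries lie between 691644 and 1010888 ends and the shCTRL libraries between 131430 and 927413.

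Break ends were denser at promoters and exons than in the genome at large, though much of the promoter share lay in the densest regions. Windows within 1 kb of a protein-coding transcription start site (TSS) make up 1.55% of the genome. They held 14.6 ± 1.59% of the ends in shHMGB1 and 14.5 ± 2.69% in shCTRL (SD, n = 8 each). With each position counted once, their share was 3.56 ± 0.326% in shHMGB1 and 4.12 ± 0.530% in shCTRL. Without the densest regions, a setting chosen after seeing the data, it ran from 2.79% to 4.23% over the 16 libraries. Exons make up 3.77% and held 10.8 ± 2.23% of the ends in shHMGB1 and 13.1 ± 1.41% in shCTRL. Intergenic sequence makes up 54.6% and held 35.6 ± 1.78% of the ends in shHMGB1 and 32.9 ± 1.03% in shCTRL. Its share rose in shHMGB1 by 2.68 percentage points (exact permutation p = 0.00463, adjusted over 8 tests 0.0370). The exon share was 2.22 points lower in shHMGB1, a difference that did not pass the correction (exact p = 0.0231, adjusted 0.0926). The low values lay mostly in replicate 2 of shHMGB1, at 9.41 ± 2.01%, against 12.3 ± 1.44% in its replicate 1 and 12.6 ± 1.22% and 13.5 ± 1.64% in replicates 1 and 2 of shCTRL (SD, n = 4 each). Intronic ends, at 39.0 ± 1.25% and 39.5 ± 2.49%, did not differ detectably (adjusted exact p = 0.686).

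For the share of break ends in intergenic sequence, shHMGB1 against shCTRL, the call ended when each position was counted once (adjusted p = 0.0714), with at most 3 ends per position (0.0782) and without the densest regions (0.0586), all exact permutation tests. The differences there were larger, at 3.68, 3.69 and 3.36 points against 2.68. It ended with the replicate block (0.0938). It also ended without shCTRL 0 Gy replicate 2 (adjusted exact p = 0.0617), shCTRL 3 Gy replicate 1 (0.0617), shCTRL 3 Gy replicate 2 (0.130), shHMGB1 0 Gy replicate 2 (0.0617) or shHMGB1 3 Gy replicate 2 (0.0988). The exon difference passed without shHMGB1 0 Gy replicate 1 (adjusted exact p = 0.0309), shHMGB1 3 Gy replicate 1 (0.0494) or shHMGB1 10 Gy replicate 1 (0.0185).

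The TSS share depended on how positions with many ends were treated. With each position counted once it was 3.56 ± 0.326% in shHMGB1 and 4.12 ± 0.530% in shCTRL, and the difference of −0.56 points passed the test (SD, n = 8 each; adjusted exact p = 0.0247). It was also lower in shHMGB1 with at most 3 ends per position (−0.72 points, adjusted exact p = 0.0370) and without the densest regions (−0.41 points, adjusted exact p = 0.0357), both chosen after seeing the data. Counting all ends, the difference was 0.11 points with an adjusted exact p of 0.920. With each position counted once, the share was 4.96% in the smallest library, shCTRL 3 Gy replicate 2. In larger shCTRL libraries it was 3.65% (3 Gy replicate 1), 3.58% and 3.45% (10 Gy replicates 1 and 2). The shHMGB1 libraries held 3.05% to 4.16%. Distinct positions were not compared at equal library size, so that test cannot separate the line from library size.

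Irradiated libraries held 11.4 ± 2.19% of their ends in exons against 13.5 ± 1.01% in unirradiated ones (SD, n = 12 and 4; exact p = 0.0459, adjusted 0.122). Their TSS share was 15.002 ± 2.21% against 13.3 ± 1.39% (adjusted exact p = 0.365). Without the densest regions the TSS share was 0.49 points lower after irradiation (adjusted exact p = 0.0357), a setting chosen after seeing the data. Intergenic and intronic shares moved by 1.02 and −0.68 points (adjusted exact p = 0.376 and 0.686). No region was shown to respond to irradiation differently in the 2 lines (lowest exact p 0.162, adjusted p = 0.596 for all 4 regions). The few arrangements of labels at 0 Gy left this test little power.

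**Figure D2:**
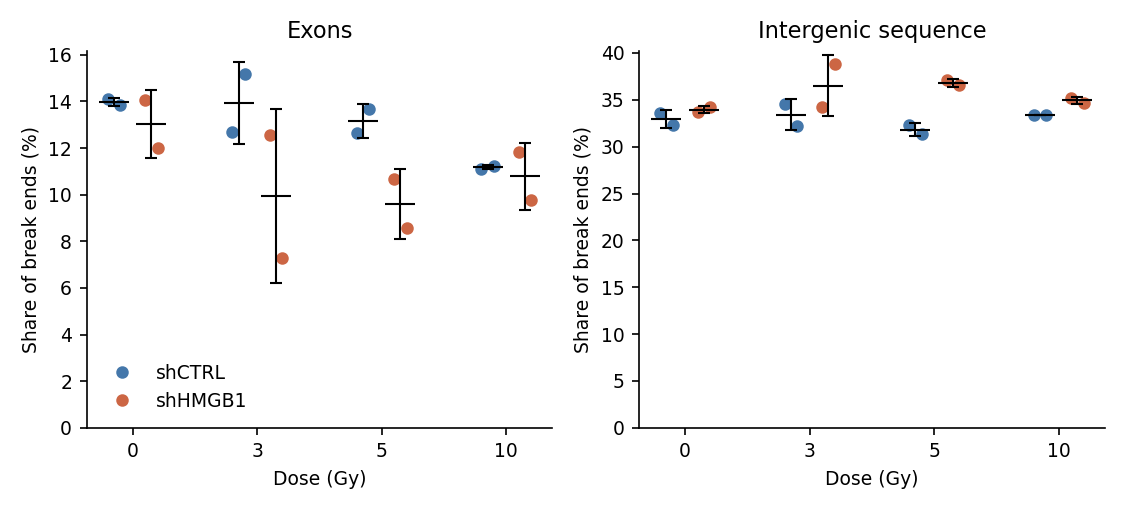
Share of break ends (%, y axes) in exons and in intergenic sequence against dose (Gy, x axes); points are libraries, bars the mean ± SD of 2. Exon shares range from 7.30% to 15.2% and intergenic shares from 31.3% to 38.8%.

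The densest genes in unirradiated shCTRL cells lay in repeats and at hosts of small nucleolar RNAs. Gm10800, a predicted gene beside satellite-like repeats (chromosome 2, 98666547 to 98667301), led with 89348 ± 21796 CPM per kb (SD, n = 2). Gm26917, at a ribosomal RNA repeat on chromosome 17 (39843013 to 39846341), had 9653 ± 5106. AY036118 and Gm42418 lie at the same locus, and Gm10718, Gm10722, Gm11168 and Gm26870 lie together at the start of chromosome 9. Gm10801, Gm12238 and Gm21738 were the other predicted genes among the 15. The snoRNA host genes Snhg6 (1089 ± 754), Snhg1 (1021 ± 400), Gas5 (961 ± 304) and Snhg12 (703 ± 277) completed the list. Reads in repeats and multicopy genes cannot be assigned to one copy, so the values of the predicted genes are uncertain. The Gm10800 log2 fold, shHMGB1 against shCTRL, was 0.09, but with each position counted once it was −0.72 (adjusted p = 0.00166). The number of positions in this short, crowded gene is capped by its length. Distinct positions per library were 1.71 times higher in shHMGB1, so the second value can reflect library size alone.

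Small RNA genes took up far more ends than their length. Genes for snoRNAs, guides of RNA modification in the nucleolus, held 1.43% to 4.81% of a library's ends, 221 to 741 times their share of the genome. Their share was 2.13 ± 0.574% in shHMGB1 and 2.84 ± 1.04% in shCTRL (SD, n = 8 each; exact p = 0.111, adjusted over 10 tests 0.222). MicroRNA genes held 0.0529 ± 0.0105% and 0.0736 ± 0.0122%, and the share fell by 0.0207 points in shHMGB1 (adjusted exact p = 0.0309). Annotated ribosomal RNA genes held 0.714% to 1.81% (adjusted exact p = 0.270). Neither snRNA nor scaRNA genes differed past the correction between lines (adjusted exact p = 0.364 and 0.0849), and no class did so with irradiation (lowest adjusted exact p = 0.220).

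Across gene lists fixed before the data were examined, exon density was highest in the highly transcribed, fibroblast and ribosomal protein lists. Exons of the highly transcribed genes, such as Actb, held 18.9 ± 4.75 CPM per kb, and introns 4.66 ± 1.35 (SD over 16 libraries). Exons of the fibroblast genes, mainly matrix genes such as Col1a1, held 9.22 ± 1.99 and introns 1.54 ± 0.304. Col1a1 and Col1a2 are in both the fibroblast and the highly transcribed list. Ribosomal protein genes had 4.77 ± 1.68 in exons and 2.02 ± 0.569 in introns. Immediate early genes, induced within minutes of stimulation, had 1.96 ± 0.474 and 1.78 ± 0.378. Markers of blood cells, listed as a possible admixture, had 0.555 ± 0.115 and 0.217 ± 0.0432, above the large genes at fragile sites (0.345 ± 0.0680 and 0.243 ± 0.0204) in exons. Their exon over intron ratio of 2.70 was above that of the ribosomal protein genes (2.34). Neuronal genes had 0.263 ± 0.0521 in exons and 0.241 ± 0.0246 in introns. Olfactory receptors had 0.262 ± 0.0428 and 0.243 ± 0.0400, and vomeronasal receptors 0.244 ± 0.0424 and 0.207 ± 0.0362.

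**Figure D3:**
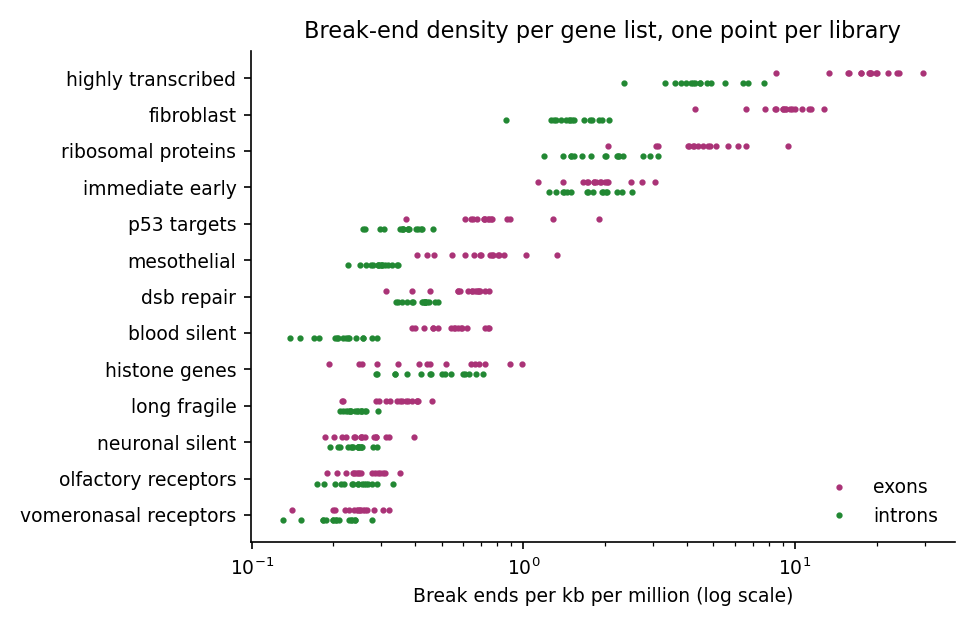
Break-end density (CPM per kb, log x axis) in exons and introns of each gene list, one point per library. Exon density averages 18.9 for the highly transcribed genes and 0.244 for the vomeronasal receptors.

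Between the lines, 10 genes gained and 21 genes lost break ends in shHMGB1 among 12582 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Under size factors from DESeq2 the split was 6 and 22. Ccn5, a secreted matrix-associated protein of the CCN family (chromosome 2, 163820861 to 163833146), fell from 91.9 ± 31.3 to 30.8 ± 19.6 CPM (SD, n = 8 each). Its log2 change was −1.58 ± 0.20 (SE; adjusted p = 6.4e-08). Neat1, the long noncoding RNA that scaffolds paraspeckles (chromosome 19, 5824708 to 5845478), fell from 691 ± 133 to 374 ± 113 (−0.85 ± 0.15, adjusted p = 0.000433). Tspan11, a tetraspanin membrane protein (chromosome 6, 127887589 to 127953977), fell from 165 ± 39.2 to 86.1 ± 23.0 (−0.86 ± 0.15, adjusted p = 0.000742). Il1rl1, the receptor for interleukin-33, fell from 121 ± 24.8 to 65.1 ± 23.4 (−0.86 ± 0.17, adjusted p = 0.00372). The fall of these 4 genes had the same sign at 4 of 4 doses.

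The other named genes that lost ends had varied roles. Thbs2, the matrix protein thrombospondin 2, changed by −0.72 ± 0.15 (adjusted p = 0.0116) and Adamtsl5, a secreted matrix protein, by −1.66 ± 0.38 (0.0259). Calr, the endoplasmic reticulum chaperone calreticulin, changed by −0.76 ± 0.16 (adjusted p = 0.00672) and Fkbp2, an endoplasmic reticulum prolyl isomerase, by −1.64 ± 0.35 (0.0122). Eif3a, a subunit of translation initiation factor 3, changed by −0.69 ± 0.14 (0.00672). Atf5, a stress-related transcription factor that overlaps Nup62 and Il4i1, changed by −1.11 ± 0.24 (0.0159). Most of that difference came from replicate 2 of shCTRL, with 61.2 to 137 CPM. Replicate 1 of shCTRL held 22.1 to 39.5, and the shHMGB1 libraries 14.6 to 33.2. Lncppara, a long noncoding RNA, changed by −0.70 ± 0.16 (0.0204). Cldn34c1, one of several near-identical claudin genes on chromosome X, changed by −1.96 ± 0.33 (0.000264), and its share of ends is uncertain because reads can be split among the copies. Outside the main setting, the calls ended in 10 of 26 settings for Lncppara, 8 of 25 for Adamtsl5, 7 of 24 for Fkbp2, 7 of 26 for Atf5, 6 of 27 for Calr, 5 of 26 for Eif3a, 5 of 27 for Thbs2 and 2 of 26 for Cldn34c1.

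Several of the genes that gained ends held few ends. Ddc, the enzyme that makes dopamine from DOPA (chromosome 11, 11814101 to 11898144), rose from 11.6 ± 7.79 to 27.5 ± 5.77 CPM (1.31 ± 0.29 SE, adjusted p = 0.0204; SD, n = 8 each). Apol6, an apolipoprotein L family member (chromosome 15, 77044729 to 77057106), rose from 2.58 ± 5.29 to 14.7 ± 6.20 (adjusted p = 0.00188). Hmox1, heme oxygenase 1, rose from 1.99 ± 2.86 to 9.30 ± 4.62 (adjusted p = 0.0493). For Apol6 and Hmox1 both shCTRL libraries at 0 Gy held 0 ends, so their fitted changes of 3.81 and 3.09 depend on the prior count. The same holds for Fbxo10, with 0 ends in both shCTRL libraries at 5 Gy. Muc4, a membrane mucin, rose by 0.73 ± 0.16 (adjusted p = 0.0204) and Mboat2, a lysophospholipid acyltransferase, by 0.73 ± 0.17 (0.0221). Fbxo10, an F-box protein, rose by 2.23 ± 0.51 (0.0259), and Scn1a, a neuronal sodium channel, by 0.84 ± 0.21 (0.0452). Spns3, a spinster family transporter, rose by 0.64 ± 0.16 (0.0452), and Cox16, a cytochrome oxidase assembly factor, by 0.75 ± 0.19 (0.0493). With each position counted once, Mboat2 turned to −0.088 (adjusted p = 0.937) and Muc4 was at 0.16. Outside the main setting, the calls ended in 21 of 25 settings for Cox16, 17 of 26 for Spns3, 17 of 25 for Scn1a, 17 of 24 for Hmox1, 9 of 26 for Muc4, 9 of 25 for Fbxo10, 6 of 25 for Ddc and 2 of 25 for Apol6. For Mboat2, 8 of 26 settings ended the call and 2 more turned its sign. Ends are not told apart by strand, so ends that Apol6 shares with Mb, Muc4 with Muc20, Fbxo10 with Polr1e or Cox16 with Adam4 count for both genes.

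**Figure D4:**
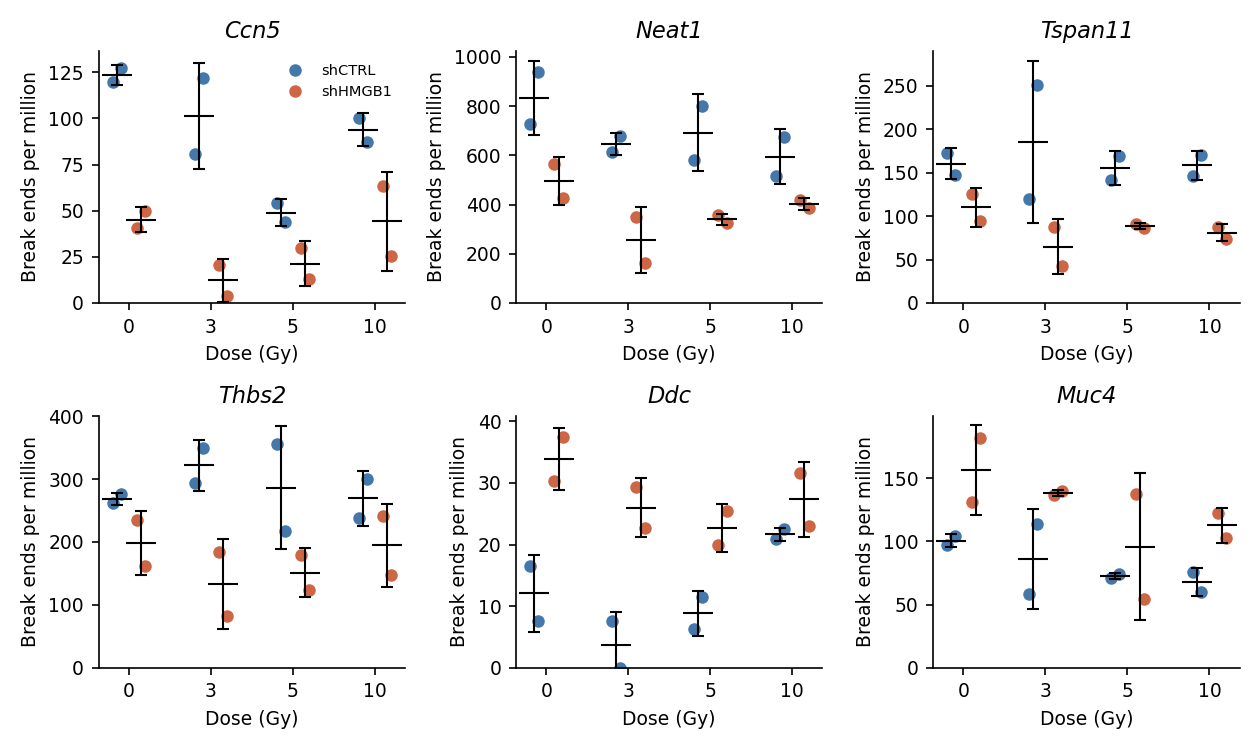
Break-end CPM (y axes) by dose (Gy, x axes) for 6 genes; points are libraries and bars the mean ± SD of 2. Ccn5 averages 91.9 in shCTRL and 30.8 in shHMGB1, and Ddc 11.6 and 27.5.

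At an unadjusted p under 0.05 the comparison of lines gave 1229 genes, against 629 expected by chance, and DESeq2 called 29 genes, 15 of them shared. DESeq2 gave no adjusted p to 10489 of the 12582 genes there. With libraries summed by line and number, chosen after seeing the data, 3 genes passed, Ccn5, Cldn34c1 and Fkbp2. The count of 31 became 69 with each position counted once, 21 of them shared. With ends within 2.5 kb of a TSS it was 19, and of the 31 genes 11 were tested there and 1 kept its call. Ccn5 lost its call there (−0.49, adjusted p = 0.769). Leaving out single libraries moved it to 7 (shHMGB1 0 Gy replicate 2), 13 (shCTRL 5 Gy replicate 2), 16 (shCTRL 0 Gy replicate 2) and 17 (shHMGB1 10 Gy replicate 2). It was 18 without shCTRL 10 Gy replicate 2 or shHMGB1 10 Gy replicate 1, 19 without shHMGB1 5 Gy replicate 1, 20 without shCTRL 5 Gy replicate 1 and 139 without shHMGB1 3 Gy replicate 1. Il1rl1, Neat1 and Tspan11 kept their call in each setting in which they were tested except the summed libraries. The Neat1 log2 fold, shHMGB1 against shCTRL, was −0.85 there (adjusted p = 0.373).

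As groups, the transcribed lists fell and the vomeronasal receptor and neuronal lists rose in shHMGB1 by camera with its preset correlation. Highly transcribed genes had a median log2 change of −0.31 over 26 members (adjusted p = 5.3e-08; adjusted p = 0.306 with an estimated correlation). Of these, 2 fell over all genes tested, Neat1 and Ncl (nucleolin, −0.66 ± 0.16 SE, adjusted p = 0.0347), and 9 fell adjusted over the list alone. Malat1, a nuclear noncoding RNA, was at −0.31 ± 0.18 (adjusted p = 0.576). Ribosomal protein genes had a median of −0.29 over 43 members (adjusted p = 9.7e-08; adjusted p = 0.306 with an estimated correlation). Of these, Rpl27a fell (−0.59 ± 0.15, adjusted p = 0.0452), and 5 genes fell adjusted over the list alone. Outside the main setting the call ended in 18 of 26 settings for Rpl27a and in 14 of 27 for Ncl. The lists share 3 genes, Rpl3, Rpl4 and Rps2.

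Fibroblast genes had a median of −0.21 over 12 members (camera adjusted p = 0.0294, and 0.484 with an estimated correlation). Col1a2 was at −0.28 ± 0.15 SE (edgeR adjusted p = 0.526). Col1a1 and Col1a2 are also members of the highly transcribed list, so the 2 lists are not separate evidence. Exon density of the fibroblast list in replicate 1 was 8.47 to 9.97 CPM per kb in shCTRL and 8.54 to 11.3 in shHMGB1. In replicate 2 it was 9.05 to 12.8 in shCTRL and 4.27 to 9.55 in shHMGB1. Vomeronasal receptors had a median of 0.33, with 53 of 68 members above 0 (adjusted p = 0.00182; adjusted p = 0.484 with an estimated correlation). Neuronal genes had a median of 0.21 over 17 members (adjusted p = 0.0333; adjusted p = 0.621 with an estimated correlation), with Rbfox1, a neuronal splicing factor, at 0.22 ± 0.14 (adjusted p = 0.649). The neuronal call ended in 12 of 20 other settings, the fibroblast call in 5 of 20 and the vomeronasal call in 1 of 20. For the list fibroblast median log2 fold, shHMGB1 against shCTRL, these included leaving out shCTRL 3 Gy replicate 2 (adjusted p = 0.0882), shHMGB1 0 Gy replicate 2 (0.117) or shHMGB1 10 Gy replicate 2 (0.0937). Over all lists, 3 passed without shCTRL 3 Gy replicate 2 and 8 without shCTRL 10 Gy replicate 1, against 5 with all libraries. In the fibroblast, vomeronasal and neuronal lists, 0 members passed edgeR over all genes or adjusted over the list alone, against 1229 genes at an unadjusted p under 0.05 and 29 by DESeq2 among all genes. The exon share was lower in the same libraries (10.8% against 13.1%). The receptor families hold near-identical copies, so their ends are uncertain by gene.

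In the other 7 lists no shift between the lines passed camera. Large genes at fragile sites had a median of 0.23 over 27 members (adjusted p = 0.0612), olfactory receptors 0.31 over 10 (0.125) and markers of blood cells, a possible admixture, 0.36 over 6 (0.179). Double-strand break repair genes had a median of 0.17 over 21 members (adjusted p = 0.568), with Xrcc4, a partner of DNA ligase IV, at 0.44 ± 0.14 SE (adjusted p = 0.244). Mesothelial genes had −0.01 over 12 (0.526) and immediate early genes −0.09 over 9 (0.527), though the fitted median of the latter was 0.06. Targets of p53 had a median of 0.03 and a mean of 0.04 over 13 members, with the test pointing down against an all-gene median of 0.08 (adjusted p = 0.568). Histone genes had fewer than 5 tested members and were not tested. With ends within 2.5 kb of a TSS the medians were 0.09 for highly transcribed and 0.00 for ribosomal protein genes, and 0 of the 3 testable lists passed camera, with 0 at an unadjusted p under 0.05.

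With irradiation 2 genes passed the threshold, averaged over lines and doses, and 8 of 80 splits of the libraries, the real one included, gave at least as many. With a replicate block within each line, chosen after seeing the data, 19 genes passed, both of these among them. Doses exchanged only within a line and number gave at least as many in 2 of 80 splits, the real one included, and 20 in the highest other. Apol8, an apolipoprotein L family member (chromosome 15, 77747798 to 77757003), rose from 2.37 ± 0.827 to 23.1 ± 10.2 CPM (SD, n = 4 and 12; log2 change 3.10 ± 0.51 SE, edgeR adjusted p = 0.000461). Taco1, an activator of mitochondrial translation (chromosome 11, 106066061 to 106073612), fell from 133 ± 18.2 to 71.3 ± 25.9 (−0.89 ± 0.18, adjusted p = 0.0132). The 16 libraries gave 877 genes at an unadjusted p under 0.05, against 629 expected by chance, and DESeq2 called 0 genes, with 517 at an unadjusted p under 0.05. Taco1 lost its call in 7 of 26 other settings, among them distinct positions (−0.34, adjusted p = 0.826) and without shCTRL 0 Gy replicate 1 (0.177), shHMGB1 0 Gy replicate 1 (0.238) or shHMGB1 0 Gy replicate 2 (0.0544). Apol8 lost its call in 2 of 26, within 2.5 kb of a TSS and by DESeq2. The edgeR count was 1 without either unirradiated shHMGB1 library and 12 without shHMGB1 3 Gy replicate 1. It was 4 to 6 without either shCTRL 0 Gy library, shCTRL 3, 5 or 10 Gy replicate 2, either shHMGB1 5 Gy library or shHMGB1 10 Gy replicate 2.

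Of the gene lists, the large genes at fragile sites rose with irradiation, with 27 of 27 members above 0 and a median of 0.19 (camera adjusted p = 0.00437; adjusted p = 0.651 with an estimated correlation). Examples are Cntnap2 at 0.28 ± 0.17 and Lrp1b at 0.30 ± 0.17 (SE), neither past the test alone (adjusted p = 0.764 and 0.737). Ribosomal protein genes fell, with a median of −0.25 (adjusted p = 0.00437; adjusted p = 0.651 with an estimated correlation) and 3 members lower adjusted over the list alone. Vomeronasal receptors rose, with a median of 0.13 and 47 of 68 members above 0 (adjusted p = 0.00437; adjusted p = 0.651 with an estimated correlation). Exon shares were lower in the irradiated libraries (11.4% against 13.5%). All 3 calls ended without shCTRL 0 Gy replicate 2, where 0 lists passed camera and 0 had an unadjusted p under 0.05. The ribosomal call also ended with ends outside exons and dense regions (adjusted p = 0.480), a setting chosen after seeing the data.

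The remaining lists did not pass with irradiation. Targets of p53, the main transcriptional responders to DNA damage, had a median of 0.11 (adjusted p = 0.415), with Sesn1 at 0.06 ± 0.27 SE (adjusted p = 0.980). Immediate early genes had 0.05 (0.331), repair genes −0.05 (0.415), highly transcribed genes −0.09 (0.331), fibroblast genes −0.09 (0.374) and neuronal genes 0.10 (0.331). Blood cell markers had 0.25 (0.356), and mesothelial genes 0.04 (0.444), turning to −0.01 under size factors from DESeq2. Olfactory receptors had −0.12 (0.558), but 0.15 without shCTRL 3 Gy replicate 1, when 52 of them were tested (adjusted p = 0.0149). Any library left out lets more receptors pass the filter, and their median was then above 0.

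The response to irradiation differed between the lines in 0 genes by edgeR and in 0 by DESeq2, with 655 at an unadjusted p under 0.05 by edgeR. In simulated data of this design 0% of the genes with a 2-fold difference in response were recovered, so the design had little power for single genes. Of the gene lists, 3 differed by camera. Highly transcribed genes (median −0.47, adjusted p = 0.00188; adjusted p = 0.591 with an estimated correlation) and ribosomal protein genes (−0.50, 0.00188; adjusted p = 0.591 with an estimated correlation) responded lower in shHMGB1. Olfactory receptors responded higher (0.80 over 10 members, adjusted p = 0.0319; adjusted p = 0.591 with an estimated correlation). All 3 calls ended with ends outside exons and dense regions and without shCTRL 0 Gy replicate 1. Repair genes had a median of −0.01 although the test pointed up (adjusted p = 0.891), and the lowest adjusted p among the other lists was 0.148, for immediate early genes.

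At single doses, Ccn5 fell in shHMGB1 at 3 Gy (log2 change −2.69 ± 0.45 SE, edgeR adjusted p = 0.000472). At 5 Gy, Fkbp2 (−3.31 ± 0.67, adjusted p = 0.0328) and Tmem201, an inner nuclear membrane protein (−2.35 ± 0.49, adjusted p = 0.0328), fell. The 5 Gy count was 0 with library totals, distinct positions, at most 3 ends per position, ends near the TSS, only the 4 libraries compared or DESeq2, and the Ccn5 call at 3 Gy ended near the TSS and with only the 4 libraries compared. Tmem201 pointed the other way at 0 Gy (0.68) and 10 Gy (1.23), and its 5 Gy value rested on 43.7 and 112 CPM in the 2 shCTRL libraries of that dose. Fkbp2 held few ends, with 29.1 and 72.4 CPM in shCTRL at 5 Gy against 2.21 and 7.63 in shHMGB1. At 10 Gy its values overlapped between the lines (24.5 and 10.6 against 6.92 and 15.7). At 0 and 10 Gy 0 genes passed edgeR or DESeq2, with 633 and 336 at an unadjusted p under 0.05 by edgeR. Left-out libraries moved the count at 3 Gy to 44 (shCTRL 3 Gy replicate 1), 7 (shHMGB1 3 Gy replicate 1), 2 (shCTRL 3 Gy replicate 2) and 0 (shHMGB1 3 Gy replicate 2, 581 at an unadjusted p under 0.05). At 5 Gy it was 0 without shCTRL 5 Gy replicate 2 or shHMGB1 5 Gy replicate 1 and 4 to 19 without each other library, except shCTRL 10 Gy replicate 1, shHMGB1 5 Gy replicate 2 and shHMGB1 10 Gy replicate 1. Whether the doses differ from one another was not tested.

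On the scale of 1 Mb windows, 4 of 2578 windows lost ends in shHMGB1 and 0 gained (edgeR; 438 at an unadjusted p under 0.05; DESeq2 was not run on windows). The window with the Cldn34c1 to Cldn34c3 claudin genes (chromosome X, 123000001 to 124000000) fell from 77.7 ± 17.7 to 43.3 ± 9.73 CPM (SD, n = 8 each; log2 −0.96 ± 0.15 SE, adjusted p = 0.000941). A window inside Cdh13, a large cadherin gene (chromosome 8, 118000001 to 119000000), fell from 448 ± 48.4 to 349 ± 35.3 (−0.43 ± 0.09, adjusted p = 0.0256). Windows at the end of chromosome Y from 90000001 (−0.73 ± 0.15, adjusted p = 0.0307) and on chromosome 18 from 36000001, with the Pcdha protocadherin cluster (−0.39 ± 0.08, adjusted p = 0.0406), also fell. The claudin window held in all 25 other settings, while the call ended in 9 of 25 for the Cdh13 window, 14 of 25 for the window on chromosome Y and 18 of 25 for that on chromosome 18. With libraries summed by line and number only the claudin window passed. The count was 217 without shCTRL 3 Gy replicate 1, 150 without shHMGB1 3 Gy replicate 1, 10 without shCTRL 0 Gy replicate 1, and 1 or 2 without any other library except shCTRL 3 Gy replicate 2.

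The windows closest to the threshold in the other direction included that of Scn1a on chromosome 2 from 66000001 (0.36 ± 0.09 SE, adjusted p = 0.116). With irradiation 0 windows passed edgeR, against 372 at an unadjusted p under 0.05 (DESeq2 was not run on windows). With the replicate block within each line, chosen after seeing the data, 52 passed, reached in 2 of 80 splits that kept line and number, the real one included, and the highest other split gave 136. The lowest adjusted p was 0.0940, for a window without protein-coding genes on chromosome 4 from 67000001 (0.47 ± 0.10 SE). Without shHMGB1 3 Gy replicate 1 the count with irradiation was 9, without shCTRL 3 Gy replicate 2 it was 5, and without shCTRL 0 Gy replicate 2 it was 1.

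Pairs of break-end positions were compared at the spacing of neighbouring nucleosomes. The ratio of position pairs 170 to 200 bp apart to pairs 80 to 110 bp apart was 0.763 ± 0.0256 in shHMGB1 and 0.765 ± 0.0240 in shCTRL (SD, n = 8 each; exact permutation p = 0.861). It ran from 0.714 to 0.815 over the 16 libraries. No value expected without nucleosomes was computed, so the ratio compares libraries and does not show whether nucleosomes add or remove pairs. Irradiated libraries had 0.760 ± 0.0252 and unirradiated ones 0.777 ± 0.0153 (SD, n = 12 and 4; exact p = 0.233). Without shCTRL 3 Gy replicate 2 that difference was −0.0227 (exact p = 0.0391). With ends outside exons and dense regions, chosen after seeing the data, the ratio was 0.555 ± 0.0206 in shHMGB1 and 0.516 ± 0.0445 in shCTRL (exact p = 0.0293). In irradiated libraries it was 0.545 ± 0.0237 there, against 0.506 ± 0.0643 in unirradiated ones (exact p = 0.0421). Both lines had a lower ratio there than over all ends. The value over all ends thus depended on pairs within exons and dense regions, and it says little about spacing elsewhere. Within lines in that setting, shCTRL had 0.537 ± 0.0236 irradiated and 0.451 ± 0.0110 unirradiated (SD, n = 6 and 2). The shHMGB1 values were 0.553 ± 0.0231 and 0.561 ± 0.0135. The difference of the irradiation response between lines was −0.0943 there (exact p = 0.306) and −0.0322 counting all ends (exact p = 0.123). The lines were thus not shown to differ in that response.

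A stretch of chromosome 4 held almost no ends in either line, and it was chosen after its values were seen. From 88500001 to 89900000, where Cdkn2a lies, the windows of 100 kb held 5.04% of the chromosome's median in shCTRL and 5.80% in shHMGB1. No test of the stretch was made.

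**Figure D5:**
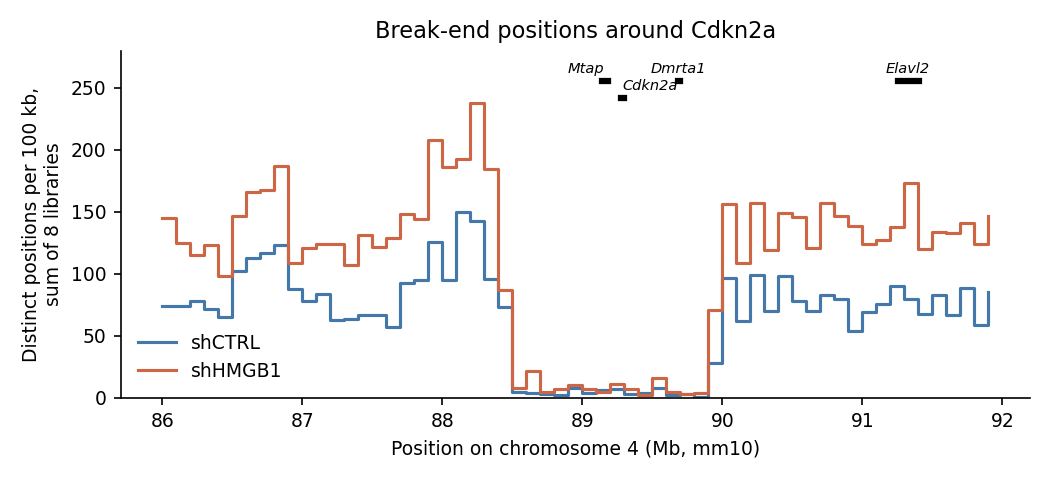
Distinct break-end positions per 100 kb window (sum of 8 libraries, y axis) along chromosome 4 (Mb, x axis) in shCTRL and shHMGB1. Between 88500001 and 89900000 the mean is 4.29 in shCTRL and 8 in shHMGB1, against chromosome medians of 85 and 138.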

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

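The lists themselves were fixed before the data were examined, and the comparison with ends outside exons and dense regions was chosen after the results were seen. The irradiation response differed between the lines in 3 gene lists by camera with its preset correlation. The difference, shHMGB1 minus shCTRL, had a median log2 of −0.47 for highly transcribed genes, −0.50 for ribosomal protein genes and 0.80 for olfactory receptors. With an estimated correlation the adjusted p was 0.591 for each list. With ends outside exons and dense regions 0 lists passed, with 2 at an unadjusted p under 0.05, and the olfactory list had only 10 members with enough ends.

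Chance was weighed by refitting the gene and window comparisons on 80 splits of the libraries, the real one included. For genes between the lines, the real split called 31 and the highest other 14, so only the real split reached that count. Chance can be excluded only if the single libraries of a line are independent units. The splits exchanged libraries without keeping a number together, so they do not rule out a difference between cultures or preparations, and 3 genes passed with libraries summed by line and number. For windows between the lines the real split called 4 and the highest other 4, so 2 of the 80 splits reached it. That share is low, but another split gave as many windows and the count fell without most single libraries. Only the claudin window passed with libraries summed by line and number, so chance is not excluded for the 4 windows. For genes with irradiation the real split called 2 and the highest other 33, and 8 splits reached it, so chance cannot be excluded. A split with 33 calls points to a structure of the samples other than irradiation. The replicate number within a line is such a structure (80 genes in shCTRL and 49 in shHMGB1), and whether it made those 33 calls was not tested. With a replicate block within each line, chosen after seeing the data, 19 genes and 52 windows passed with irradiation. Of 80 splits that kept line and number, 2 reached each count, the real one included, but the highest others were 20 and 136, so this setting does not replace the result above. For genes in the interaction and for windows with irradiation the real count was 0 by edgeR, all 80 splits reached it, and the highest others were 2 and 8; at an unadjusted p under 0.05 there were 655 genes and 372 windows, and DESeq2 called 0 genes.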

How the results depend on the processing

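The settings with ends outside exons and dense regions, with at most 3 ends per position (shares, genes, windows) and shares without dense regions were chosen after seeing the data. The planned pairing of ends on the same strand was not run, since the files keep no strand. Totals by line, irradiation and dose kept their direction and side of the threshold in each setting other than left-out libraries. The cause of a change was not tested unless stated.

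The TSS share in shHMGB1 turned to −0.56 points with distinct positions, −0.72 with at most 3 ends per position and −0.41 without dense regions, and with irradiation to −0.49 without dense regions. The intergenic difference was 3.68, 3.69 and 3.36 points in those 3 settings, no longer past the adjusted threshold. The spacing differences turned to 0.0392 (line) and 0.0383 (irradiation) with ends outside exons and dense regions. Mboat2 turned to −0.088 with distinct positions and −0.16 with at most 3 ends per position, and Gm10800 to −0.72 and −0.65.

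For genes, shHMGB1 against shCTRL, the count was 69 with distinct positions and 19 near the TSS, where only 1293 genes were tested. With irradiation the 2 genes became 4 by library totals, 6 without a filter, 4 with ends outside exons and dense regions, 1 with at most 3 ends per position, and 0 near the TSS (82 at an unadjusted p under 0.05) or by DESeq2 (517). At 0 Gy 1 gene passed with ends outside exons and dense regions. At 3 Gy 0 passed by edgeR near the TSS (104 at an unadjusted p under 0.05) or with only the 4 libraries compared (288). For genes, shHMGB1 against shCTRL at 5 Gy, 6 passed without a filter, 4 with ends outside exons and dense regions, and 0 by edgeR with library totals (937), distinct positions (931), near the TSS (70), at most 3 ends per position (1042) or only the 4 libraries compared (858), and 0 by DESeq2 (594). With an estimated correlation 0 lists passed camera in the comparison of lines (1 at an unadjusted p under 0.05), irradiation (0) and interaction (0), and likewise near the TSS; the interaction had 0 with ends outside exons and dense regions (2 at an unadjusted p under 0.05).

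Windows between lines numbered 17 by library totals, 10 at 100 kb, 11 with distinct positions, 7 without a filter and 2 with ends outside exons and dense regions. With irradiation they numbered 2 at 100 kb and 3 with ends outside exons and dense regions.

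Over the 28 pairs of groups, same-numbered libraries deviated together with r between −0.0966 and 0.0679, 0 of them over 0.1, the level set for using the numbers as pairs. Within a line they nevertheless shared a structure (80 genes by number in shCTRL, 49 in shHMGB1), a hint from the data and not the design. With the replicate number as a block, 39 genes passed between lines, including all 31, and 3 with irradiation. The replicate block ended the call for the share of break ends in intergenic sequence, shHMGB1 against shCTRL (2.68 points, adjusted exact p = 0.0938), gave 1 window with irradiation and changed no other count past 1.5 times. A block within each line, which in the comparison of lines does not allow for numbers being the units of a line, gave 134 genes between lines, 19 with irradiation, 19 at 3 Gy and 50 at 5 Gy, and 186 and 52 windows. With libraries summed by line and number, 3 genes and 1 window passed between lines. Both were chosen after seeing the data.

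Leaving out single libraries, where a group keeps 1 library assumed to vary like the others, gave the ranges below. The filter on low counts was set again each time and lets more genes with few ends pass. Ranges for genes and lists therefore mix the missing library with a looser filter. Totals: log2 0.38 to 1.08 between lines, 0.12 to 0.41 with irradiation, and slopes of 0.08 to 0.14 in shCTRL and 0.01 to 0.04 in shHMGB1. Shares between lines: exons −2.88 to −1.56 points and intergenic 2.10 to 3.26. Spacing with irradiation: −0.0227 to −0.0136. Genes: 7 to 139 between lines, 1 to 12 with irradiation, 0 to 1 in the interaction, and 0 to 1, 0 to 44, 0 to 19 and 0 to 0 at 0, 3, 5 and 10 Gy. The list olfactory_receptors median log2 fold, irradiated against 0 Gy, ranged from 0.0077 to 0.237. Lists: 3 to 8 between lines, 0 to 4 with irradiation and 0 to 4 in the interaction. Windows: 1 to 217 between lines and 0 to 9 with irradiation. Of the 400 results for called genes with a library left out, 266 kept their call, 134 lost it and 0 reversed. Of the 244 in other settings, 175 kept it, 67 lost it and 2 reversed.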

Other observations

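A stretch of chromosome 4 without a test in the design was almost empty of ends, and it was chosen after its values were seen. From 88500001 to 89900000 (mm10), 14 windows of 100 kb held a mean of 4.29 distinct positions over the shCTRL libraries and 8 over the shHMGB1 libraries. That is 5.04% and 5.80% of the chromosome's median window. The stretch holds 37 protein-coding genes, among them the type I interferon cluster, the methylthioadenosine phosphorylase gene Mtap, and Cdkn2a and Cdkn2b, which encode inhibitors of cell cycle kinases. Cdkn2a held 0 positions in shCTRL and 4 in shHMGB1, Cdkn2b 1 and 0, and Mtap 3 and 2. Elavl2, the next large gene on that side, held 122 and 243. Of the other tumour suppressors examined, Bap1 held 23 and 31 positions and Nf2 197 and 229. Runs of at least 5 windows under 20% of the median numbered 18 on the autosomes, and many of the others hold repeated gene families such as Vmn1r, Vmn2r, Mup and Skint. This stretch was 1 of those in which 0 of the windows were empty.

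Chromosomes differed in their level of distinct positions per 1 Mb window. Levels are medians over a chromosome's windows, relative to the median of all windows with enough positions. Chromosome X stood at 0.548 ± 0.0134 in shCTRL and 0.569 ± 0.0285 in shHMGB1 (SD, n = 8 each), and chromosome 19 at 1.40 ± 0.0379 and 1.35 ± 0.0267. Only 1 window of chromosome Y held enough positions, the window at its end.

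In the following weighing of 3 patterns, the tests of library size and of a single small library were chosen before their results were seen and all the others after. The first pattern is the crowding of ends on snoRNA genes and on exons of transcribed genes. Copies of a molecule left at single positions are argued against, because with each position counted once snoRNA genes still stood at least 78.6-fold above the genome mean. Cellular RNA carried into the libraries may contribute, since the density inside snoRNA genes was at least 58.8 times that of their flanks, and exons of highly transcribed genes at least 3.53 times as dense as their introns, in every library. DNA breaks tied to transcription may contribute too, since introns of highly transcribed genes were at least 8.10 times as dense as those of neuronal genes in every library. Intronic RNA would give the same value, so both stay open.

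The second pattern is the lower share of ends in exons of shHMGB1 libraries, which lay mostly in replicate 2 (9.41% against 12.3% in replicate 1, with 12.6% and 13.5% in shCTRL). A fall of all exons alike is argued against, because the share in exons of olfactory and vomeronasal receptor genes was higher by 0.22 on the log2 scale (exact p = 0.0386) while that of highly transcribed genes was lower (−0.42, exact p = 0.0154). A smaller RNA-derived part is a candidate explanation that cannot be told apart here, since the snoRNA share was lower without passing the test (exact p = 0.111). Library size stays open too, because the exon share fell with the log2 total within shCTRL (r = −0.839, exact p = 0.00548, adjusted over 2 lines 0.0110; rho −0.690, exact p = 0.0694; r without the 2 farthest libraries −0.907) but not within shHMGB1 (r = 0.134, exact p = 0.751; rho 0.143, exact p = 0.752; r without the 2 farthest 0.913). A change in transcription or chromatin with the HMGB1 hairpin was not tested.

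The third pattern is the larger number of ends in shHMGB1 libraries. More ends from exons and dense regions are argued against as the whole cause, because the difference stayed with both left out (1.74-fold, exact p = 0.0123). The exon share was already lower in shHMGB1 (10.8% against 13.1%), so leaving exons out was unlikely to end the difference. Intronic RNA and repeats outside the dense regions were left in, so RNA-derived or repeat-derived ends there stay open. A single small library is argued against as the whole cause, because a smaller difference passed the test without shCTRL 3 Gy replicate 2 (log2 0.38 against 0.73, exact p = 0.0386), though much of the size rested on that library. More cells or deeper sequencing of shHMGB1 libraries cannot be told apart from more breaks per cell, since neither number is used here, and the ends per distinct position differed by only −0.0542 (exact p = 0.167). More breaks in cells carrying the hairpin against HMGB1, whose level was not checked here, therefore may be one explanation among those left open, as may a difference between 2 cultures or preparations of each line.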
